A study of Homo sapiens with 8 samples.

How the data were processed

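RNA abundance was measured by sequencing of polyA RNA in LU99, a human non-small cell lung cancer cell line. Cells had been kept for 3 or 5 days in DMSO, the vehicle, or in 1 uM MRTX1719, an inhibitor of the arginine methyltransferase PRMT5 that binds together with methylthioadenosine. The 8 libraries fell into 4 groups of 2 by treatment and day, as their titles give them. RNA was extracted from frozen pellets with a Qiagen RNeasy Plus Universal kit and libraries were made with the NEBNext Ultra II RNA kit, per the labels' protocols.

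The deposited values were read counts per Ensembl gene, not normalized, in 1 table with 1 column per library. The submitters' processing notes name the GRCh38 genome build, Trim Galore 0.6.3 and Picard 2.20.3. The aligner, the counting tool, the gene annotation, the strand setting and the treatment of duplicate reads are not given in the sources used here. Every column matched the title of 1 library. Of 60675 genes in the table, 57055 matched GENCODE 29 by Ensembl identifier, which gave positions on GRCh38, transcript GC content and transcript length. A strand setting could not be read from the sources, so reads of overlapping and antisense genes cannot be told apart. Reads of near-identical genes such as HSPA1A and HSPA1B, of FTH1 with its pseudogenes, of ribosomal proteins and of HLA genes are uncertain for the same kind of reason.

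Library totals ran from 36494298 to 43401293 reads, and 3 reads, the upper limit that a count of 0 allows, correspond to 0.0691 to 0.0822 CPM, reads scaled by library total. Intervals on single counts are exact Poisson intervals at the 95% level and cover counting error only. The labels do not say that the replicates of a group were separate cultures, so p-values measure the spread between these libraries, which may be technical.

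Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 17013 genes, TMM factors were applied, and each group had 1 coefficient in a fit of all 8 libraries (estimateDisp, glmQLFit and glmQLFTest). Contrasts were MRTX1719 against DMSO at day 3, the same at day 5, the difference of these effects between the days, and DMSO at day 5 against DMSO at day 3. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene passed at an adjusted p under 0.05. CPM values were scaled by TMM factors of the 8 libraries unless the text says otherwise; sums over a list were not scaled. Log2 fold changes are given with their standard errors (SE).

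The groups, the fit, the contrasts, 36 gene lists and the rule for naming genes were set before the data were examined. The lists covered PRMT family and methylosome partners, methionine and polyamine metabolism, spliceosome core proteins, SR proteins and hnRNPs, DNA replication and E2F targets, G2 and mitosis, homologous recombination and Fanconi anaemia repair, p53 targets, CDK inhibitors and D cyclins, the BCL2 family, ATF4 and amino acid response, ER chaperones, heat shock proteins, interferon-stimulated genes, MHC class I, NF-kB targets, cholesterol synthesis and fatty acid synthesis. They further covered ribosomal proteins, ribosome biogenesis, nuclear and mitochondrial genes of oxidative phosphorylation, glycolysis and hypoxia, MAPK output, immediate early genes, YAP targets, NRF2 targets, mesenchymal, epithelial and lung lineage genes, lysosome and autophagy, replication-dependent histones, snoRNA host genes, and immune, endothelial and fibroblast markers. Lists with at least 5 tested members entered camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists; 35 lists did, and the immune list had 2 tested members. Camera was repeated with the correlation estimated per list, and fry, which asks whether the genes of a list move one way on balance, was run beside it. For each list the gene test was also adjusted over the list alone.

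Genes were named by this rule. For each treatment comparison it took the 12 largest rises and 12 largest falls among genes past the test with an average log2 CPM of at least 2, an official symbol and no overlap between the groups; 6 of each were taken for the other contrasts. In each list past camera, or with at least 1 in 3 of its tested members past the test, it took up to 4 members with the smallest p and up to 2 that moved the opposite way. It always took 12 preset genes: PRMT5, WDR77, MTAP, CDKN2A, CDKN2B, MAT2A, MDM2, MDM4, CDKN1A, CCND1, MYC and MKI67. The text names fewer genes of the first and second kind, keeping the largest changes and the smallest p. A result the rule names for the difference between the days is not reported here.

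DMSO day 5 replicate 2 stood apart from the other libraries. The fit without it was among the alternatives set beforehand, but the decision to describe genes and lists from that fit of 7 libraries was made after the data were seen, on the library's GC content trend and its correlation with the other libraries. In that fit DMSO at day 5 is a single library, which is assumed to vary like the other groups. The counts of the fit of 8 libraries are given first for each comparison, and the naming rule was applied to both fits. Common biological coefficients of variation were 0.272 with 8 libraries and 0.062 with 7.

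The test was checked on simulated counts drawn from the real means and totals of 17013 genes, of which 67 were changed 1.5-fold, 67 2-fold and 66 4-fold. The simulated counts had the spread of the fit of 7 libraries, and DMSO day 5 replicate 1 gave the mean of DMSO at day 5. The simulation thus assumes that this library stands for its group. Its rates therefore cannot vouch for the real day 5 calls. The simulated genes were also drawn independently of one another. The random lists below thus cannot show how camera treats lists of correlated genes. With the profile of DMSO day 5 replicate 2 in the simulated data, the fit of 8 libraries recovered 0% of genes changed 2-fold and 36.4% of genes changed 4-fold at day 3. Without that library it recovered 80.6% of genes changed 1.5-fold, 95.5% changed 2-fold and 100% changed 4-fold at day 3, and 73.1%, 85.1% and 98.5% at day 5. Of unchanged genes, 4.75% at day 3 and 4.4% at day 5 then had an unadjusted p under 0.05, and 0 of 34 random lists passed camera. In the same simulation 22 unchanged genes at day 3 and 12 at day 5 passed after adjustment, beside 54, 64 and 66 recovered genes at day 3 and 49, 57 and 65 at day 5, a share of false calls above the 0.05 aimed at.

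Alternatives set beforehand were DESeq2 1.42.0, limma-voom, RLE factors, library totals alone, no filter on low counts, a filter of 1 CPM in 4 libraries, thinning to 36494298 reads, robust dispersion, only the libraries of a contrast, a replicate block, each library left out in turn, camera with an estimated correlation, and fry. Chosen after seeing the data were removal of a lowess trend on GC content per library (span 0.3), limma-voom with library weights, and repeats of the fit of 7 libraries under several of these settings and with each further library left out.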

Results

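Transcript abundance was measured in LU99 lung cancer cells after 3 or 5 days with DMSO or with 1 uM MRTX1719, in 2 libraries for each of the 4 groups. Library totals lay between 36494298 and 43401293 reads. Replicates differed by more than sampling noise in every group, with a chi-square per degree of freedom of 4.06 for DMSO and 5.77 for MRTX1719 at day 3, and 414 and 7.77 at day 5, so each library was counted once.

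DMSO day 5 replicate 2 stood apart from the other 7 libraries. Its log2 CPM correlated with theirs at 0.916 to 0.940 across genes, against 0.964 to 0.994 among the other 7, and the first principal component, with 53.2% of the variance, separated it. Its deviation from the other libraries rose with transcript GC content, from a median of -1.38 on the log2 scale in the 20% of genes with the lowest GC content to 0.78 in the 20% with the highest, a Spearman rho of 0.717 across genes. In the other libraries rho lay between -0.318 and -0.164. Mitochondrial genes took 0.885% of its reads, against 1.68% to 2.25% in the others. Genes and lists are described from the fit without this library, a choice made after the data were seen; the counts of the planned fit of 8 libraries are given first.

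**Figure D1:**
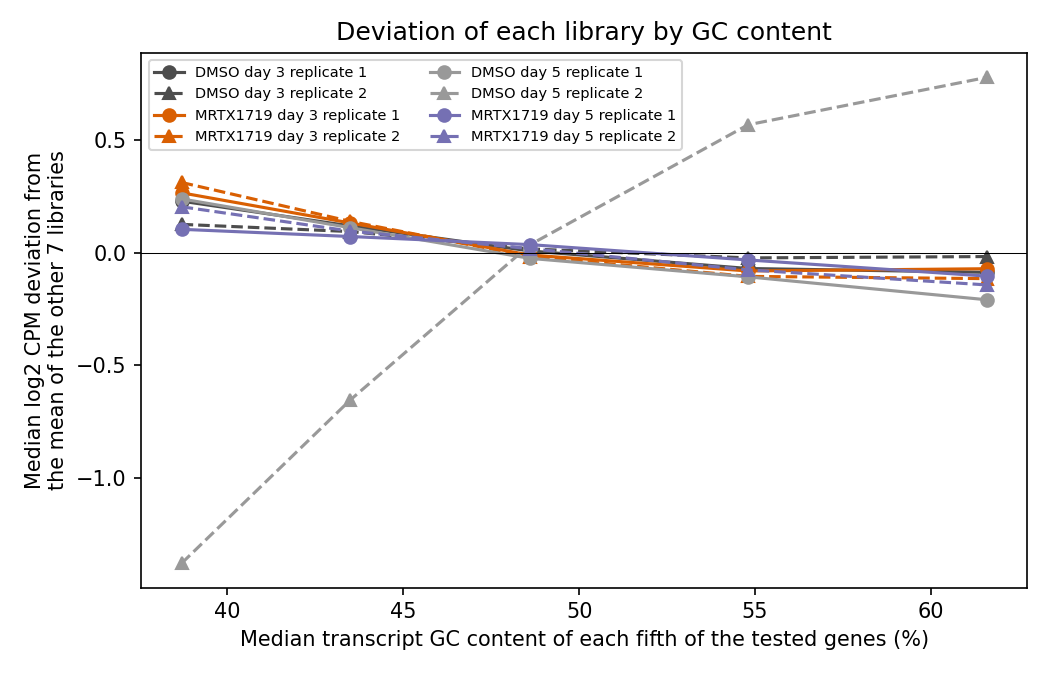
Median log2 CPM deviation of each library from the mean of the other 7, for 5 equal groups of the tested genes by transcript GC content (x axis, median GC in percent; lines join the groups of 1 library). DMSO day 5 replicate 2 runs from -1.38 to 0.78, and no other library leaves the range from -0.21 to 0.31.

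A second feature crossed the groups. Transcripts of type I and type III collagen and part of the fibroblast marker list were present in 5 libraries and nearly absent in 3. COL1A2, a chain of type I collagen, stood at 113 and 98.6 CPM in the DMSO day 3 libraries. It stood at 118 in MRTX1719 day 3 replicate 1 and 0.46 in replicate 2, at 0.644 and 0.509 in the DMSO day 5 libraries, and at 142.5 and 142 in the MRTX1719 day 5 libraries. COL1A1, the other chain, followed the same libraries. Given as CPM without TMM factors, it was at 217, 285 and 162 against 3.4 at day 3, and at 5.52 and 8.94 against 148 and 310 at day 5. Of the fibroblast list, DCN was at 5.39 to 10.7 CPM in the 5 libraries and 0.023 to 0.0539 in the 3, LUM at 1.14 to 2.87 and 0 to 0.0269, FAP at 1.35 to 2.99 and 0 to 0.023, and THY1 at 0.767 to 1.75 and 0.025 to 0.0461, all without TMM factors. FBLN1 did not follow this split, and PDGFRA and PDGFRB followed it weakly. Without TMM factors, the matrix gene FBLN1 was at 69.4, 79.7 and 134 CPM in the 3 libraries and at 72 to 113 in the 5. The growth factor receptor gene PDGFRA was at 5.9, 3.55 and 2.17 against 5.05 to 10.2, and PDGFRB at 1.18, 0.808 and 0.991 against 2.35 to 3.58. Of 15 immune cell markers only 2 could be tested, and their summed level over the list was 0.752 to 1.71 CPM in all 8 libraries. At day 5 this signal was present in both treated libraries and in neither DMSO library.

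PRMT5, the target of the compound (Ensembl gene ENSG00000100462, chromosome 14, 22920511 to 22929585 on GRCh38), was at 70.6 ± 1.92 CPM with DMSO and 78.4 ± 3.11 with MRTX1719 at day 3, and at 79.2 ± 13.2 and 70.8 ± 0.0735 at day 5 (mean ± SD, n = 2 each). MTAP, the enzyme that clears methylthioadenosine and is lost in the cancers this compound is meant for (chromosome 9, 21802543 to 21937651), had 14 and 14 reads in the DMSO day 3 libraries, 12 and 1 with MRTX1719 at day 3, 3 and 3 with DMSO at day 5, and 7 and 11 with MRTX1719 at day 5. Its neighbours on chromosome 9 were low but above the floor in most libraries. CDKN2A, a CDK inhibitor gene (21967753 to 21995301), had 27 to 62 reads per library, 0.622 to 1.58 CPM without TMM factors, and CDKN2B (22002903 to 22009363) had 3 to 24.

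The first comparison asked what 3 days of MRTX1719 changed. Genes of DNA replication fell together. RRM2, a subunit of the ribonucleotide reductase that supplies DNA precursors, stood at 155 ± 4.54 CPM with DMSO and 35.3 ± 0.313 with MRTX1719. MYBL2, a transcription factor of cycling cells, stood at 108.2 ± 0.598 and 22.5 ± 0.779 (mean ± SD, n = 2 each). Targets of p53 rose: CDKN1A, the CDK inhibitor p21, went from 174 ± 8.01 to 418 ± 10.5 CPM, MDM2, the ubiquitin ligase that restrains p53, from 38.3 ± 2.99 to 105 ± 3.28, and the stress cytokine GDF15 from 52.7 ± 1.77 to 203 ± 2.65. These directions come with calls in the fit of 7 libraries and not in the fit of 8.

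In the fit of 8 libraries, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower at day 3. Its smallest adjusted p was 0.0524, and 2034 genes had an unadjusted p under 0.05. DESeq2 called 76 higher and 112 lower, and limma-voom 3 and 1. A fit of only the 4 day 3 libraries called 3534 higher and 3700 lower. Leaving out DMSO day 5 replicate 2 gave 3349 higher and 3532 lower, leaving out DMSO day 5 replicate 1 gave 3416 and 3484, and leaving out MRTX1719 day 3 replicate 1 gave 0 and 1. Of the 6881 genes called with 7 libraries, 6820 were also called in the same direction from the 4 day 3 libraries alone. Camera placed 4 lists higher and 8 lower with 8 libraries, and 8 higher and 8 lower with 7.

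With 7 libraries, all 42 tested members of the DNA replication and E2F target list fell, 42 also when adjusted over the list alone, with a median log2 fold change of -1.34 and a camera adjusted p = 0.008 with an estimated correlation. Among them were the thymidine kinase gene TK1 (-1.97, SE 0.059), the helicase component GINS2 (-2.07, SE 0.080), and E2F1 and E2F2, transcription factors of S phase entry (-2.05, SE 0.073, and -2.14, SE 0.135). All 35 members of the G2 and mitosis list fell (35 adjusted over the list alone), with a median of -0.76 and a camera adjusted p = 0.0303 with an estimated correlation. KIF20A, a mitotic kinesin, was at -1.17 (SE 0.051), and MKI67, the proliferation marker, fell by 1.03 on the log2 scale. Of 36 genes of homologous recombination and Fanconi anaemia repair 29 fell and 2 rose (29 and 2 adjusted over the list alone), with a camera adjusted p = 0.0691 with an estimated correlation. BRCA1 was at -1.30 and the exonuclease gene EXO1 at -1.57, while RAD50, of the break-sensing MRN complex, was at 0.63. With 8 libraries 0 members of these lists passed over all genes, and 40, 18 and 10 fell when adjusted over the list alone. Their camera adjusted p with an estimated correlation were then 0.00153, 0.092 and 0.294.

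Of 29 p53 targets 21 rose and 5 fell (21 and 5 adjusted over the list alone), with a median of 0.59 and a camera adjusted p = 0.0691 with an estimated correlation. MDM2 was at 1.45 (SE 0.072), CDKN1A at 1.26 (SE 0.052) and GDF15 at 1.94 (SE 0.058), and SESN2, an antioxidant stress gene, fell by 0.45 on the log2 scale. With 8 libraries 0 of the 29 passed over all genes and 9 rose when adjusted over the list alone. Genes of the ATF4 amino acid response mostly fell, 17 of 26 with 4 higher (17 and 4 adjusted over the list alone; camera adjusted p = 0.184 with an estimated correlation). They included PSAT1 of serine synthesis at -1.32 and the secreted factor STC2 at -1.15, while DDIT3, the stress factor CHOP, was at 0.53. Of 28 lysosome and autophagy genes 14 rose and 5 fell (14 and 5 adjusted over the list alone; camera adjusted p = 0.463 with an estimated correlation). The protease gene CTSL was at 1.34 and the cholesterol transporter gene NPC1 at 1.18. Of 21 genes of MAPK output 14 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 0.184 with an estimated correlation). The feedback regulators DUSP4 and SPRY4 were at 1.24 and 0.94, and the growth factor gene HBEGF at -0.94.

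Most genes of RNA processing and ribosome assembly that passed were lower. Of 38 spliceosome core genes 19 fell and 1 rose (22 and 1 adjusted over the list alone; median -0.23; camera adjusted p = 0.301 with an estimated correlation). LSM4 was at -0.78 and SF3B1 at 0.42. Of 33 SR protein, hnRNP and CLK kinase genes 16 fell and 6 rose (17 and 7 adjusted over the list alone; camera adjusted p = 0.35 with an estimated correlation). HNRNPL was at -0.69 and CLK1 at 0.44. Of 30 ribosome biogenesis and MYC target genes 17 fell and 1 rose (19 and 2 adjusted over the list alone; camera adjusted p = 0.301 with an estimated correlation). BOP1 was at -0.70 and MYC itself at -0.76. Of 38 nuclear genes of oxidative phosphorylation 23 fell and 0 rose (25 and 0 adjusted over the list alone; camera adjusted p = 0.534 with an estimated correlation). The remaining lists past camera moved up. They were heat shock proteins (9 of 13 higher, 10 adjusted over the list alone), the BCL2 family (8 higher and 2 lower of 16, with 8 and 2 adjusted over the list alone), NRF2 targets (10 higher and 5 lower of 21, with 11 and 6 adjusted over the list alone), epithelial genes (9 higher and 2 lower of 19, with 9 and 2 adjusted over the list alone) and endothelial markers (3 higher and 1 lower of 7, with 3 and 1 adjusted over the list alone). Their camera adjusted p with an estimated correlation were 0.312, 0.282, 0.484, 0.301 and 0.282. With 8 libraries camera did not pass heat shock proteins (adjusted p = 0.101), NRF2 targets (0.15), epithelial genes (0.0507), endothelial markers (0.0515) or SR protein and hnRNP genes (0.0869).

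The largest rises outside these lists were IGFN1 (2.22, SE 0.12), DEPP1, a gene induced by FOXO factors (2.12, SE 0.116), the urea transporter gene SLC14A1 (1.99, SE 0.080), the neuropeptide precursor VGF (1.99, SE 0.067) and the clock repressor BHLHE41 (1.95, SE 0.114). Of the preset genes, WDR77, the partner of PRMT5 in the methylosome, fell by 0.73 on the log2 scale (SE 0.078), PRMT5 was at 0.15 (SE 0.054) with an edgeR Benjamini-Hochberg adjusted p = 0.0447, CCND1 at 0.20 and MDM4 at 0.28. MAT2A (0.12), CDKN2A (-0.22), CDKN2B (-1.30) and MTAP (-0.96) did not pass. Of the 10 tested fibroblast markers 1 fell and 0 rose (1 and 0 adjusted over the list alone), and the list passed camera downward with 8 libraries (adjusted p = 0.00876; 0.529 with an estimated correlation) and not with 7 (0.105), with COL1A2 at 118 CPM in replicate 1 of MRTX1719 and 0.46 in replicate 2.

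**Figure D2:**
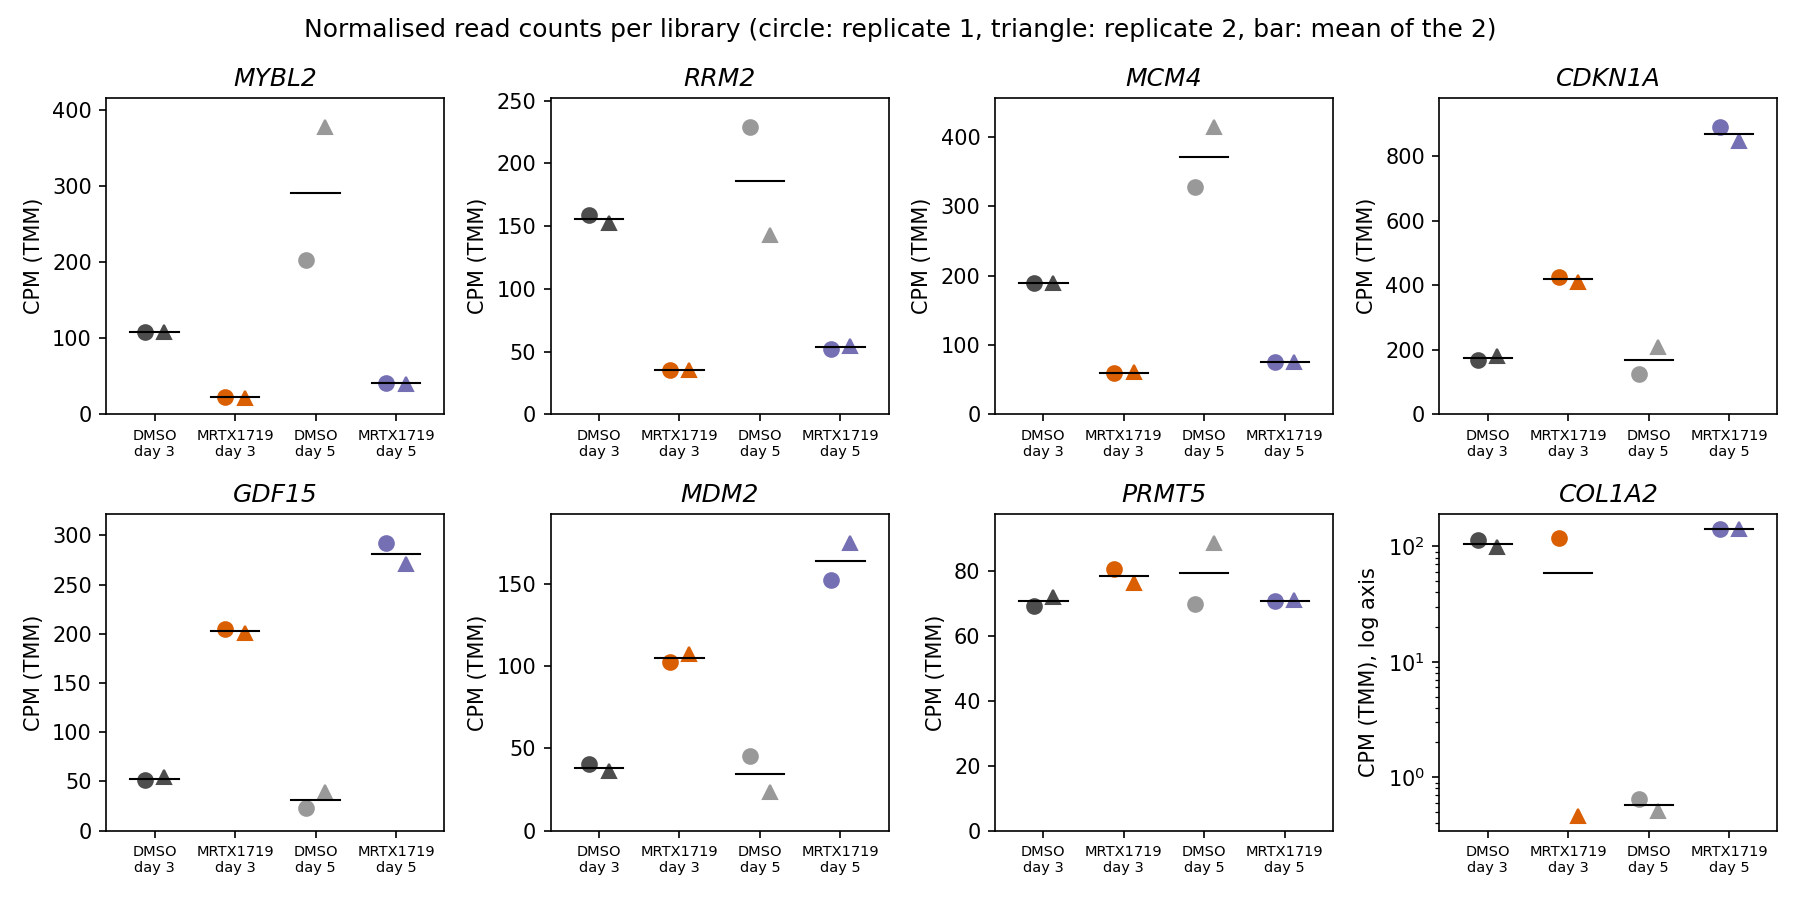
Normalised read counts (CPM with TMM factors, y axis; log axis for COL1A2) of 8 genes in each library, by group (x axis); circles are replicate 1, triangles replicate 2 and bars the mean of the 2. MYBL2 stood at 108.2 CPM with DMSO and 22.5 with MRTX1719 at day 3, GDF15 rose on both days, PRMT5 lay between 69.2 and 88.5 in all 8 libraries, and COL1A2 was nearly absent in MRTX1719 day 3 replicate 2 and both DMSO day 5 libraries.

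The second comparison asked the same question after 5 days. GDF15 stood at 31.1 ± 11.2 CPM with DMSO and 282 ± 15.2 with MRTX1719, and CDKN1A at 167 ± 60.3 and 868 ± 31.9 (mean ± SD, n = 2 each). MCM4, a subunit of the replicative helicase, went from 372 ± 61.3 to 75.4 ± 0.255 CPM, and POLD1, the catalytic subunit of DNA polymerase delta, from 274 ± 127 to 37.8 ± 0.556. In the fit of 8 libraries these 4 genes passed, as did SLC14A1, the rise of which was 4.01 on the log2 scale with an edgeR Benjamini-Hochberg adjusted p = 0.00133.

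The fit of 8 libraries called 810 genes higher and 901 lower at day 5 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 called 934 and 1088, and limma-voom 879 and 834. Without DMSO day 5 replicate 2 there were 3852 higher and 4154 lower, and without DMSO day 5 replicate 1 there were 6288 and 5805. Other libraries also moved the count: 136 and 63 genes passed without DMSO day 3 replicate 1, 136 and 63 without its replicate 2, 321 and 181 without MRTX1719 day 3 replicate 1, 319 and 181 without its replicate 2, 11 and 0 without MRTX1719 day 5 replicate 1, and 2 and 0 without its replicate 2. Of the 1711 genes called with 8 libraries, 1705 were also called in the same direction with 7 and 0 had the opposite sign. Of the 8006 genes called with 7 libraries, 8 were also called from the 4 day 5 libraries alone, which include DMSO day 5 replicate 2, and 84.97% kept their sign. Camera placed 10 lists higher and 5 lower with 8 libraries and 14 and 8 with 7; without DMSO day 5 replicate 1, 8 lists passed.

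With 7 libraries 26 of 29 p53 targets rose and 0 fell (27 adjusted over the list alone), with a median of 1.01 and a camera adjusted p = 0.0338 with an estimated correlation. GDF15 was at 3.59 (SE 0.085), CDKN1A at 2.79 (SE 0.072) and MDM2 at 1.84 (SE 0.093). In the fit of 8 libraries 12 rose over all genes and 18 when adjusted over the list alone. The camera adjusted p with an estimated correlation was then 0.0253 for p53 targets. It was 0.0065 for DNA replication and E2F targets and 0.134 for G2 and mitosis. In the DNA replication and E2F target list 41 of 42 genes fell (41 adjusted over the list alone; median -1.49; camera adjusted p = 0.00768 with an estimated correlation), among them POLD1 (-2.30, SE 0.060) and MCM4 (-2.13, SE 0.058), and with 8 libraries 32 fell, 35 adjusted over the list alone. All 35 genes of G2 and mitosis fell (35 adjusted over the list alone; median -1.14; camera adjusted p = 0.0329 with an estimated correlation), with MYBL2 at -2.33 and the cyclin gene CCNA2 at -1.68, and with 8 libraries 15 fell, 18 adjusted over the list alone. Of 36 recombination and Fanconi anaemia genes 32 fell and 2 rose (32 and 2 adjusted over the list alone; camera adjusted p = 0.0862 with an estimated correlation), with FANCA of the Fanconi anaemia core complex at -2.20, EXO1 at -1.64 and RAD50 at 0.64, and with 8 libraries 9 fell and 0 rose (9 and 0 adjusted over the list alone; camera adjusted p = 0.454 with an estimated correlation).

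**Figure D3:**
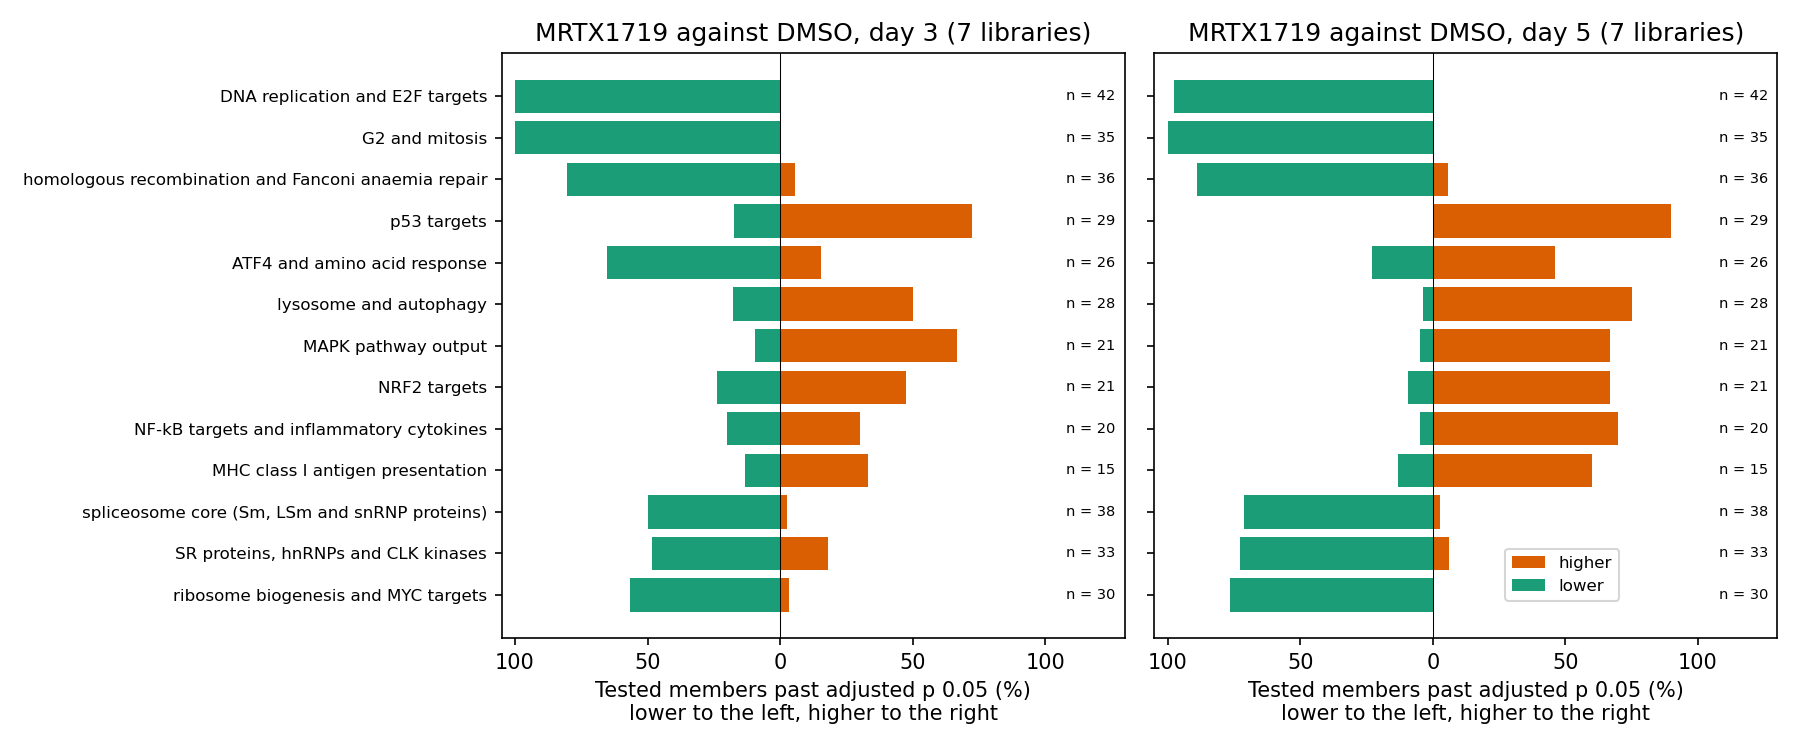
Percent of the tested members of 13 gene lists that passed the gene test with 7 libraries (x axis; lower to the left, higher to the right), for MRTX1719 against DMSO at day 3 and day 5; n is the number of tested members. DNA replication and mitosis genes lie to the left on both days, 42 of 42 and 35 of 35 at day 3, and p53 targets to the right, 21 of 29 at day 3 and 26 of 29 at day 5.

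With 7 libraries genes of cell death, antigen presentation and the lysosome were among those that rose at day 5. Of 16 BCL2 family genes 7 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.141 with an estimated correlation), with the pro-apoptotic genes BBC3 at 1.87 and PMAIP1 at 1.52 and the anti-apoptotic MCL1 at -0.36. Of 28 lysosome and autophagy genes 21 rose and 1 fell (21 and 1 adjusted over the list alone; camera adjusted p = 0.141 with an estimated correlation). NPC1 was at 2.07 and the saposin precursor gene PSAP at 1.57. Of 15 MHC class I genes 9 rose and 2 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.186 with an estimated correlation), with B2M, the light chain, at 0.97, HLA-B at 1.12 and the peptide transporter gene TAP2 at -0.61. Without DMSO day 5 replicate 1 TAP2 was at 0.55. Of 30 interferon-stimulated genes 17 rose and 4 fell (18 and 4 adjusted over the list alone; camera adjusted p = 0.137 with an estimated correlation). IFIT2 was at 2.62, IFIT3 at 1.87 and OAS3 at -0.64. Of 20 NF-kB targets 14 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 0.137 with an estimated correlation), with the adhesion molecule gene ICAM1 at 1.84 and NFKB1 at -0.24. With 8 libraries camera did not pass the MHC class I genes (1 higher and 0 lower, 2 and 0 adjusted over the list alone; adjusted p = 0.408) or the BCL2 family (4 and 0, 6 and 2 adjusted over the list alone; 0.135). It passed the lysosome, interferon and NF-kB lists with 10, 5 and 4 genes higher and 0, 2 and 0 lower (11, 7 and 5 higher and 1, 2 and 0 lower adjusted over the list alone). None of these lists passed in that fit with an estimated correlation (camera adjusted p = 0.0917 for the interferon list and 0.279 for the NF-kB list).

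Stress and signalling lists rose as well with 7 libraries. Of 21 MAPK output genes 14 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 0.137 with an estimated correlation). DUSP4 was at 1.86 and SPRY4 at 1.42. Of 21 NRF2 targets 14 rose and 2 fell (14 and 3 adjusted over the list alone; camera adjusted p = 0.141 with an estimated correlation), with the haem oxygenase gene HMOX1 at 1.72, the ferritin gene FTH1 at 1.56 and TALDO1 of the pentose phosphate pathway at -0.67. Of 26 ATF4 genes 12 rose and 6 fell (12 and 6 adjusted over the list alone; camera adjusted p = 0.279 with an estimated correlation), with DDIT4, an inhibitor of mTORC1, at 2.15, DDIT3 at 1.51 and PSAT1 at -0.76. Of 19 epithelial genes 9 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.141 with an estimated correlation), with the tight junction gene CLDN1 at 1.65 and the splicing regulator ESRP2 at -0.82. Of 75 ribosomal protein genes 35 rose and 3 fell (35 and 3 adjusted over the list alone; median 0.17; camera adjusted p = 0.751 with an estimated correlation). With 8 libraries camera did not pass the ATF4 genes (4 higher and 0 lower, 4 and 1 adjusted over the list alone; adjusted p = 0.0834), the epithelial genes (2 and 1, 4 and 1 adjusted over the list alone; 0.189) or the ribosomal protein genes (0 and 0, 0 and 0 adjusted over the list alone; 0.792). It passed MAPK output with 7 higher and 0 lower (9 and 0 adjusted over the list alone) and NRF2 targets with 4 and 1 (9 and 1 adjusted over the list alone). Neither of them passed camera in that fit with an estimated correlation.

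Genes of RNA processing and methylation fell with 7 libraries. Of 38 spliceosome core genes 27 fell and 1 rose (27 and 1 adjusted over the list alone; camera adjusted p = 0.206 with an estimated correlation). SF3B3 was at -0.66 and SF3B1 at 0.34. Of 33 SR protein and hnRNP genes 24 fell and 2 rose (24 and 3 adjusted over the list alone; camera adjusted p = 0.141 with an estimated correlation). HNRNPR was at -0.97 and HNRNPD at -0.89. Of 30 ribosome biogenesis genes 23 fell and 0 rose (23 and 1 adjusted over the list alone; camera adjusted p = 0.145 with an estimated correlation), with BOP1 at -1.14, the nucleolar protein gene NOP56 at -0.92 and MYC at -0.72. Of 12 PRMT family and methylosome genes 7 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.349 with an estimated correlation). WDR77 was at -0.98, PRMT6 at -0.74 and PRMT2 at 0.48. Of 20 methionine and polyamine genes 11 fell and 2 rose (11 and 2 adjusted over the list alone; camera adjusted p = 0.361 with an estimated correlation), with ADI1 of methionine salvage at -0.87, AMD1 of polyamine synthesis at -0.95 and the polyamine acetyltransferase gene SAT1 at 0.90; without DMSO day 5 replicate 1 AMD1 was at 0.49. With 8 libraries camera did not pass the SR protein and hnRNP genes (2 lower and 0 higher, 2 and 0 adjusted over the list alone; adjusted p = 0.0834), the PRMT family (2 and 0, 3 and 0 adjusted over the list alone; 0.0834) or the methionine and polyamine genes (2 and 1, 3 and 1 adjusted over the list alone; 0.502). It passed the spliceosome core with 2 lower (0 adjusted over the list alone) and ribosome biogenesis with 6 lower (7 adjusted over the list alone). Neither list passed in that fit with an estimated correlation (camera adjusted p = 0.0917 for each). Of the other preset genes, CCND1 (0.76) and MKI67 (-1.13) passed, and PRMT5 (0.01), MAT2A (-0.01), MDM4 (-0.24), CDKN2A (0.81), CDKN2B (2.25) and MTAP (1.48) did not.

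Matrix and stromal genes rose at day 5 along the libraries that held the collagen signal. Of 28 mesenchymal and matrix genes 21 rose and 0 fell (22 and 0 adjusted over the list alone; camera adjusted p = 0.412 with an estimated correlation), and of 10 tested fibroblast markers 9 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.572 with an estimated correlation). The largest log2 values were those of CHI3L1 (8.73, SE 2.157), MEG3 (8.63, SE 1.956), COMP (8.56, SE 2.379) and COL3A1 (8.42, SE 2.166), and MMP2 (5.79, SE 1.159) and FN1 (5.12, SE 0.992) also passed with 8 libraries. FN1, fibronectin, stood at 260.2 ± 47.6 CPM with DMSO at day 3, 14 ± 2.69 with DMSO and 425 ± 37.8 with MRTX1719 at day 5, and at 218 and 21 in the MRTX1719 day 3 libraries. Matrix genes with a smaller SE were COL5A2 (2.19, SE 0.075) and ACTA2, smooth muscle actin (2.17, SE 0.134). Of 7 endothelial markers 5 rose and 0 fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.176 with an estimated correlation). KDR, a VEGF receptor gene that these cells expressed in all 8 libraries, was at 1.25 (SE 0.083). TIE1 was at 0.72 with 7 libraries and -0.20 without DMSO day 5 replicate 1. With 8 libraries 5 of the mesenchymal and matrix genes, 1 of the fibroblast markers and 2 of the endothelial markers rose and 0 of each fell (12, 9 and 2 higher adjusted over the list alone).

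The list results at day 5 depend on which DMSO day 5 library is kept. Most lists that passed camera without replicate 2 did not pass without replicate 1 in its place. The day 5 values of named genes depend on this choice as well. Without replicate 1 in place of replicate 2 these genes changed sign or moved by at least 1 on the log2 scale, beside AMD1, TAP2 and TIE1: EXO1 was at -0.32, RAD50 at 2.03, B2M at 2.99, IFIT2 at 4.38, BBC3 at 0.85, SF3B1 at 2.16 and ESRP2 at -1.83. MCL1 was then at 0.08, PRMT2 at -0.16, PRMT5 at -0.32, MDM4 at 0.39, MAT2A at 1.17, CHI3L1 at 6.56 and COMP at 6.58. TOP2A of the G2 and mitosis list and FANCI of the recombination list moved the opposite way as well. The fall of every G2 and mitosis gene therefore rests on replicate 1. Smaller moves are not listed in full. MDM2 was then at 2.82, POLD1 at -3.27, BOP1 at -2.06 and MYC at -1.355. GDF15 was at 2.85, DDIT4 at 1.27, ICAM1 at 0.99 and FTH1 at 0.665.

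The largest falls were those of the synaptic protein gene NPTX1 (-2.48, SE 0.069) and the carbonic anhydrase gene CA2 (-2.44, SE 0.091). With 7 libraries 13 lists did not pass camera at day 5. These were CDK inhibitors and D cyclins (5 higher and 7 lower of 15; camera adjusted p = 0.361; median -0.28, mean 0.33), ER chaperones (9 and 3 of 17; 0.0992), heat shock proteins (4 and 5 of 13; 0.424), cholesterol synthesis (5 and 8 of 23; 0.525), fatty acid synthesis (7 and 3 of 14; 0.142), nuclear oxidative phosphorylation genes (3 and 17 of 38; 0.0577) and mitochondrially encoded genes (8 and 0 of 13; 0.087). The others were glycolysis and hypoxia (9 and 11 of 27; 0.586), immediate early genes (10 and 2 of 14; 0.0599), YAP targets (5 and 8 of 18; 0.41), lung lineage genes (2 and 1 of 8; 0.413), replication-dependent histones (3 and 2 of 11; 0.41) and snoRNA host genes (9 and 3 of 21; 0.377). Adjusted over the list alone, higher and lower members numbered 7 and 7, 9 and 3, 4 and 5, 5 and 8, 7 and 3, 3 and 18, 8 and 0, 9 and 11, 10 and 3, 5 and 8, 2 and 1, 3 and 2, and 10 and 4, in that order. With 8 libraries the mitochondrially encoded genes passed camera upward (median 0.64, adjusted p = 0.00803; 0.628 with an estimated correlation), with 0 of 13 genes past the gene test (0 adjusted over the list alone).

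The third comparison asked whether the effect of MRTX1719 differed between the days. In the fit of 7 libraries the rise of p53 targets was larger at day 5, with 23 of 29 genes past the test of the difference and 0 in the other direction (24 adjusted over the list alone; median 0.48; camera adjusted p = 0.103 with an estimated correlation). CDKN1A differed by 1.53 on the log2 scale (SE 0.084) and MDM2 by 0.39 (SE 0.112). Of 26 ATF4 genes 20 were shifted upward and 1 downward (20 and 1 adjusted over the list alone; median 0.74; camera adjusted p = 0.103 with an estimated correlation). Of 35 G2 and mitosis genes 22 were shifted downward (27 adjusted over the list alone; median -0.30; camera adjusted p = 0.12 with an estimated correlation). With 8 libraries the p53 and ATF4 lists passed camera and the G2 and mitosis list did not (adjusted p = 0.261).

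In the fit of 8 libraries edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes in either direction, with 1221 at an unadjusted p under 0.05; DESeq2 called 59 and 5, and limma-voom 0 and 0. Without DMSO day 5 replicate 2, 1695 genes were higher and 1574 lower, without DMSO day 5 replicate 1 5403 and 4919, without MRTX1719 day 3 replicate 1 27 and 0, and without its replicate 2 2 and 0. Leaving out DMSO day 3 replicate 2 from the 7 libraries gave 1101 and 966. Camera placed 9 lists higher and 1 lower with 8 libraries and 11 and 7 with 7, and with an estimated correlation 0 lists passed in either fit. Lysosome and autophagy genes (19 of 28 shifted upward, 20 adjusted over the list alone), NRF2 targets (12 of 21, 13 adjusted over the list alone), NF-kB targets (11 of 20, 12 adjusted over the list alone) and MHC class I genes (10 of 15, 10 adjusted over the list alone) were among the lists shifted upward, with camera adjusted p = 0.169, 0.162, 0.12 and 0.166 with an estimated correlation. Heat shock proteins were shifted downward (8 of 13, 9 adjusted over the list alone; camera adjusted p = 0.176 with an estimated correlation). With 8 libraries camera did not pass the MHC class I genes (adjusted p = 0.295) or the heat shock proteins (0.426). Of the heat shock list, HSP90AA1, HSPD1, HSPA4 and HSPA1B had opposite signs at day 5 in the fits of 8 and 7 libraries. PRMT5 (-0.14), WDR77 (-0.25), MAT2A (-0.13), MYC (0.04), MKI67 (-0.10), CDKN2A (1.03) and MTAP (2.44) did not pass. Without DMSO day 5 replicate 1 in place of replicate 2, CDKN1A differed by 0.79 and MDM2 by 1.37, and MAT2A was at 1.04 and MYC at -0.61.

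Across the 17013 genes, which are not independent replicates, the log2 fold changes of the days correlated at 0.479 with 8 libraries and 0.45 with 7 (Pearson); the comparisons share no library. With 7 libraries 2124 genes were higher on both days, where independent lists of these sizes would share 758, 2554 were lower on both days against 862, and 198 moved in opposite directions against 1617. Without DMSO day 5 replicate 1 in place of replicate 2, 2256 were higher on both days against 1263, 2442 lower on both days against 1189, and 1134 moved in opposite directions against 2453.

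The last comparison, DMSO at day 5 against DMSO at day 3, gave the change in culture without the compound. CTH, the cystathionine gamma-lyase gene of sulphur amino acid metabolism, went from 17.1 ± 0.0142 to 1.96 ± 0.573 CPM, and PAPPA2, a protease gene for IGF-binding proteins, from 11.9 ± 0.0149 to 1.61 ± 0.338 (mean ± SD, n = 2 each). SLC14A1 went from 8.27 ± 0.182 to 1.76 ± 0.0112 CPM and TRIML2 from 146 ± 1.47 to 40.2 ± 1.22. These 4 genes fell with 8 libraries, each with an edgeR Benjamini-Hochberg adjusted p = 0.0273. With 7 libraries the constitutive chaperone gene HSPA8 rose by 1.56 (SE 0.047), or by 0.48 without DMSO day 5 replicate 1 in place of replicate 2, and WDR77 by 1.04 (SE 0.087). The inducible HSPA1A and HSPA1B, near-identical in sequence and so uncertain as single genes, rose by 2.06 (SE 0.065) and 1.72 (SE 0.059). Gene lists were not tested in this comparison. TENT5B (1.64), IL7R (1.57) and KRT80 (1.55) were the other large rises, of which IL7R was at -0.14 without DMSO day 5 replicate 1 in place of replicate 2.

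In this comparison the fit of 8 libraries called 0 genes higher and 5 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 3484 at an unadjusted p under 0.05; DESeq2 called 118 and 219, and limma-voom 0 and 5. Without DMSO day 5 replicate 2 there were 3176 and 2784, without DMSO day 5 replicate 1 5507 and 6064, without DMSO day 3 replicate 1 or replicate 2 0 and 0, without MRTX1719 day 5 replicate 1 or replicate 2 0 and 0, and without MRTX1719 day 3 replicate 1 or replicate 2 0 and 18. Of the 5960 genes called with 7 libraries, 0 were also called from the 4 DMSO libraries alone, and 78.24% kept their sign. With library totals alone in place of TMM the 7 libraries gave 2357 higher and 3259 lower, and with 8 libraries the median of all genes moved to -0.18 from -0.06. The largest falls with 7 libraries were those of the genes that follow the collagen signal, which both DMSO day 3 libraries held: COL3A1 (-8.49, SE 2.153), COMP (-8.35, SE 2.407), CHI3L1 (-8.08), ELN (-7.91), MEG3 (-7.58) and COL1A2 (-7.34). With 7 libraries MDM2 (0.26), MYC (-0.26), CDKN1A (-0.47), MAT2A (-0.25) and MKI67 (0.22) passed. The values of MDM2, MYC and CDKN1A had the opposite sign without DMSO day 5 replicate 1, at -0.73, 0.38 and 0.27, and so did CCND1 at 0.40; MAT2A was then at -1.44, COMP at -6.37 and CHI3L1 at -5.92. PRMT5 (0.00), MDM4 (-0.27), CCND1 (-0.07), CDKN2A (-0.41), CDKN2B (-2.29) and MTAP (-1.98) did not pass.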

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

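Of the tests weighed here, those on the fibroblast list within day 3, on MTAP reads, on a swapped label and on GC content were chosen only after the result was seen; so was the fit of 7 libraries as the source of the differences between days.

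The MRTX1719 effect differed between day 5 and day 3 in the genes given here, by the test of the difference in the fit of 7 libraries; with 8 libraries the edgeR Benjamini-Hochberg adjusted p of these genes lay between 0.259 and 0.876. Upward differences on the log2 scale were 1.53 for CDKN1A, 0.39 for MDM2, 0.56 for CCND1 and 3.55 for CDKN2B, which had 3 to 24 reads per library. CDKN2B was at 0.192 to 0.583 CPM without TMM factors in the 5 libraries with the collagen signal and 0.0808 to 0.15 in the 3 others. Its difference therefore cannot be told apart from that split of the libraries. MDM4 differed by -0.52. These rest on DMSO day 5 replicate 1; with replicate 2 in its place CDKN1A differed by 0.79, MDM2 by 1.37, CCND1 by 0.07, CDKN2B by 2.66 and MDM4 by 0.10. Downward differences among the large ones were -2.00 for NPTX1, -1.65 for VSTM1, -1.54 for B4GALNT3, -1.40 for NAPRT and -1.33 for KRT15. In that order they were -2.755, -1.974, -2.28, -2.354 and -2.144 with replicate 2 in place of replicate 1. The largest upward differences belonged to genes of the collagen signal, at 10.18 for COMP, 9.90 for COL3A1, 9.70 for MEG3, 9.47 for CHI3L1, 9.30 for ELN and 8.62 for COL1A2, of which COMP was at 8.19 and CHI3L1 at 7.29 with replicate 2 in place of replicate 1.

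The first pattern is the collagen signal itself, present in 5 of 8 libraries and not shared by all fibroblast markers. An effect of MRTX1719 alone is argued against within day 3, where the treated libraries differed by a median of 5.433 on the log2 scale over the tested fibroblast list, against 0.3 between the DMSO libraries. A DMSO library under the label of MRTX1719 day 3 replicate 2 is argued against by its replication genes, which lay at 1.017 on a scale from 0 at DMSO to 1 at the other treated library. Reads from cells other than LU99, with fibroblasts as a candidate source, stay open. MTAP had 12 reads in MRTX1719 day 3 replicate 1 and 1 in replicate 2, a rate ratio of 13.2. This sets 2 single libraries against counting error and decides nothing. It was put in place of an earlier test that pooled 5 libraries against 3 by their measured signal. MTAP was at 0.178 to 0.342 CPM without TMM factors in these 5 libraries and at 0.025 to 0.0808 in the 3. Since the signal chose the libraries and the counts lie near the floor, this is no test of the source. In a second list of fibroblast transcripts written before its test, 9 of 28 tested genes were higher in each of the 5 libraries than in each of the 3, against 1.7% of all tested genes; this is short of the bound of 50% set beforehand and above that of 20%, so the source stays open.

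The second pattern is the distance of DMSO day 5 replicate 2 from the other libraries. Loss of long transcripts beyond the GC trend is argued against by a rho of 0.021 between its deviation and transcript length once that trend was removed. Before removal the rho was -0.156, so a loss that runs along with GC content cannot be excluded. A mislabelled treated library is argued against by the replication genes of this library, at 0.029 on a scale from 0 at the other DMSO library to 1 at the treated ones. A GC content bias of the library may account for part of it, with a rho of 0.717 across genes. Removing the trend lowered the SD of the log2 difference between the day 5 DMSO libraries from 1.15 to 0.751, against 0.341 between the day 3 DMSO libraries, so another part stays open. A difference between the cultures was not tested, since the group holds only these 2 libraries.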

How the results depend on the processing

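The settings tried are named in the processing text; the 7-library repeats, the GC trend and the library weights were added after the data were seen. The 201 gene results the text draws on are a subset of the 456 named by the rule, chosen after the values were seen. Each setting, the fit of 7 libraries among them, was compared with the fit of 8 libraries. The values described above from 7 libraries were not the baseline. A value counted as the same may thus have passed in neither fit. Under all settings the 201 kept call and direction in 6 cases, with 3984 values the same, 1866 stronger, 322 weaker and 25 reversed; all 456 gave 8592, 4657, 703 and 143, and 23 of them reversed at least once. Of 99 list results 17 kept call and direction, with 2353 values the same, 320 stronger, 143 weaker and 16 reversed. For every change below the cause was not tested.

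Genes higher and lower at day 3 were 76 and 112 with DESeq2, 3 and 1 with limma-voom, 14 and 27 with library totals, 28 and 44 without a filter, 3 and 4 with the stricter filter, 3534 and 3700 with only the contrast's libraries, 1215 and 1355 with the GC trend removed, and 3570 and 3623 with library weights. With 7 libraries they were 2541 and 2970 (DESeq2), 3383 and 3627 (limma-voom), 3541 and 3675 (GC), and 3139 and 3645 (totals). Leaving out libraries gave 0 to 3547 and 0 to 3722. At day 5 they were 8 and 0 with only the contrast's libraries, 2769 and 3296 (GC) and 106 and 267 (weights). With 7 libraries they were 3049 and 3394 (DESeq2), 3614 and 4140 (limma-voom), 4004 and 4413 (GC), and 3724 and 4207 (totals), and leaving out libraries gave 2 to 6288 and 0 to 5805. For the difference between days they were 59 and 5 (DESeq2), 18 and 1 (no filter), 288 and 208 (GC) and 1 and 1 (weights). With 7 libraries they were 1318 and 1194 (DESeq2), 1584 and 1551 (limma-voom), 1717 and 1814 (GC), and 1684 and 1404 (totals), and leaving out libraries gave 0 to 5403 and 0 to 4919. For DMSO over time they were 118 and 219 (DESeq2), 1 and 18 (totals), 15 and 62 (no filter), 2192 and 1532 (GC), 2 and 4 (weights), and 0 lower with only the contrast's libraries. With 7 libraries they were 2713 and 2000 (DESeq2), 3225 and 2530 (limma-voom), 3624 and 2841 (GC), and 2357 and 3259 (totals), and leaving out libraries gave 0 to 5507 and 0 to 6064.

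With a replicate block, day 5 gave 424 and 388 genes and DMSO over time 0 lower; with the block and 7 libraries the counts were 3108 and 3348 at day 3, 3541 and 3784 at day 5, 1469 and 1226 for the difference, and 2645 and 2394 over time, 17 lists passed for the difference, MDM2 over time was at 0.277, MYC at -0.263, and the recombination list had an adjusted p of 1.5e-05 for the difference. Differences between paired replicate numbers correlated at 0.017, 0.153, 0.004, -0.049, -0.02 and -0.13 between groups. These values show no pairing by number, but they rest on a single difference per group and cannot exclude it.

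Lists past the test at day 3 numbered 1 with an estimated correlation, 2 with it and 7 libraries, and 24 with fry and 7 libraries. At day 5 they numbered 2, 3 and 31 in that order, 23 (GC), 23 (7 libraries, totals), and 8 to 23 with libraries left out. For the difference they numbered 0, 0 and 20, 6 (fry, 8 libraries), 16 (GC), 20 (7 libraries, GC), 18 (7 libraries, totals), and 7 to 20 with libraries left out. The correlation between days was 0.167 (DESeq2), 0.132 (no filter), 0.155 (7 libraries, DESeq2) and 0.124 to 0.497 with libraries left out. Values over time reversed against the fit of 8 libraries were those of MDM2, MYC and CDKN1A. With 7 libraries MDM2 was at 0.269 (DESeq2) and 0.234 (GC), and it ran from -0.725 to 0.35 with libraries left out. MYC was at -0.248 (DESeq2), -0.259 (limma-voom), -0.234 (GC) and -0.321 (totals) with 7 libraries, and at 0.375 without DMSO day 5 replicate 1. These 7-library values have the sign of those described above from 7 libraries, 0.26 for MDM2 and -0.26 for MYC. CDKN1A ran from -0.504 to 0.269 with libraries left out. At day 5 with libraries left out AMD1 ran from -0.992 to 0.49, TAP2 from -0.694 to 0.546 and TIE1 from -0.195 to 0.741. Adjusted p of lists with fry and 7 libraries were 0.0227 for heat shock proteins, 0.0287 for lung lineage and 0.0227 for histones at day 5. For the difference, recombination genes had 0.015 (fry), 0.000257 (GC), 9.55e-06 (totals) and 8.5e-06 to 0.989 with libraries left out, G2 and mitosis 1.03e-13 to 0.366, and ribosomal proteins 4.54e-05 to 0.939.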

Other observations

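The test on single-exon genes was set before its result was seen, except for its use of the bootstrap error, which was added after.

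WDR77 was lower with MRTX1719 on both days, at 11.7 ± 0.202 against 19.3 ± 0.347 CPM at day 3 and 20.1 ± 0.338 against 40.9 ± 2.41 at day 5, while it rose between the days with DMSO, by 1.04 on the log2 scale with 7 libraries.

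PRMT5 methylates Sm proteins of the spliceosome, so a hypothesis was that MRTX1719 lowers the yield of spliced transcripts, which would leave genes with 1 exon relatively higher. At day 5 the median log2 fold change of 280 protein-coding genes with 1 exon, histones left out, was 0.106, at percentile 96.2 of 10000 random sets of genes with more exons matched on expression, whose central 95% ran from -0.052 to 0.113. The bound as first written, a median inside that range, counted against the hypothesis. A further condition, that the median lie below 0.113 by more than its bootstrap SE of 0.04, was added after the value was seen and was not met, so the result is given as undecided. At day 3 the median of the genes with 1 exon was 0.055, at percentile 93.4 of its random sets, whose central 95% ran from -0.052 to 0.069.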
